A study of Mus musculus with 34 samples.

How the data were processed

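RNA from mouse material was measured by sequencing in 34 samples. The 6 culture libraries come from embryonic stem cells kept for 4 days without leukemia inhibitory factor (LIF), the cytokine that holds these cells undifferentiated: 3 from the wild-type line CJ9 and 3 from a line labelled 4x polyA KI, both of the strain 129S1/SVImJ. Per the labels, mRNA was isolated with beads and the libraries were stranded. The embryo libraries come from laser-captured pieces of cryosections of C57/B6 embryos at embryonic day 7, amplified by Geo-seq, a protocol for small captured regions, and they are labelled heterozygous (Evx1as+/-) or homozygous (Evx1as-/-). Tables were deposited for 30 samples. The other 4, posterior embryo pieces, have no table here and were left out.

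The authors deposited 1 gene table per library in FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), with an interval for each value, in the column format of Cufflinks. The processing notes in the labels name CASAVA, TopHat2 version 2.0.11 and the genome mm10, and no version of the tool that made the values. Gene positions in the embryo tables match mm10. Those in the culture tables do not and match positions of the build before it, so each position below is given as its own table gives it. The tables hold no read counts and whole reads could not be recovered from the values, so the depth of the libraries is unknown, no counting intervals or detection floors are given, and a model of counts was not run. Whether counting used the strand is not stated. This bears on Evx1 and Evx1as, which overlap on opposite strands. Values of an identifier listed more than once in a table were added, and values below 1e-06 FPKM were set to 0.

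Groups were taken from the labels. The cultures form 2 groups of 3. The streak sections are 6 heterozygous and 5 homozygous libraries and the mesoderm sections 3 and 5, each carrying a layer number from 1 to 11 whose direction the labels do not give. There is 1 anterior epiblast library per genotype. In 3 further sections the title and the cell type label name different regions, and these stayed out of the comparisons. The labels tie no section to an embryo. Sections of a genotype may come from the same embryo, so p-values over sections are too small.

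Values were analysed as log2(FPKM + 1) for genes with a mean of at least 1 FPKM over the libraries compared, with limma 3.58.1 in R 4.3.3: a linear model, moderated statistics with a mean-dependent prior, two-sided tests and Benjamini-Hochberg (BH) adjustment, with a threshold of 0.05 on the adjusted p. Layer entered as a number in the comparisons of genotypes. The comparison of regions was made within each genotype and layer that had both. Beside the gene counts of the comparisons stands the count after scaling every library by the median ratio of its genes to the geometric mean library, because the median log2 change of all genes was over 0.1 in size in 4 of the comparisons. For gene lists, calls after scaling are given where they differ, and counts after scaling are given for only part of the lists where they differ. Evx1as, listed under the symbol 5730457N03Rik, and Evx1 were also compared by exact permutation tests, two-sided.

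Before the data were examined, 23 gene lists were fixed from textbook knowledge, for states of pluripotency, the streak and its derivatives, other cell types that a culture or section might hold, signalling targets, stress, metabolism and mitochondrial genes. A list of 5 sex-linked genes served as a check of labels only. The other 22 were tested where at least 3 members were measured with limma's camera, which compares a list with all other genes. It was run with its preset correlation of 0.01 between genes and again with the correlation estimated from the data, BH-adjusted over the lists of a comparison. Genes named in the text follow a rule fixed at the same time. The rule names Evx1as and Evx1 everywhere, but Evx1as did not pass the filter of the fits over sections, so it is given there only by permutation tests between genotypes. In each comparison the rule takes the 8 largest changes each way among genes past the threshold with at least 5 FPKM in the higher group and no overlap between the groups, and up to 4 members past the threshold from each list. Where fewer than 5 genes passed, it takes the 5 largest each way at an unadjusted p under 0.01, given as not past. Pseudogenes and predicted genes are left unnamed. Members of the streak, organizer, mesoderm and pluripotency lists may be named without passing.

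The fits were tested on simulated values. These were the fitted values with the tested effect set to 0, changes planted in some genes, and normal noise at each gene's residual SD. The noise was drawn independently for each gene and library, so it holds no correlation between sections or between genes. Of 100 genes changed by a log2 of 2, the fits recovered 77 in the cultures, 67 in streak, 23 in mesoderm, 90 in both regions together and 87 between regions. At a log2 of 1 they recovered 56, 10, 0, 38 and 29.

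Alternatives fixed at that time were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, median-ratio and quantile scaling, no mean-dependent prior, each library left out in turn, no layer term, layer or replicate number as a block, and the conflicting sections added by title or by cell type label. Median-ratio scaling for the list tests, leaving out the heterozygous layer 11 sections, which have the fewest genes detected, leaving out the RNA Yam1 or the genes of 4 chromosomes, and centring each chromosome were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.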

Results

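The cultures gave 6 gene tables of 37145 genes and the embryo sections 24 tables of 46785 genes. The sum of FPKM per library was 502990 to 582184 in culture and 132929 to 376860 in the sections. Between 12758 and 13073 genes reached 1 FPKM in a culture library and between 6806 and 10959 in a section. A non-coding RNA, Yam1, took 1.07% to 38.3% of all FPKM in the sections and 0 in culture. Mitochondrially encoded genes took 3.38% to 5.53% of FPKM in the 12 heterozygous sections and 2.03% to 3.21% in the 12 homozygous ones. Sequencing depth is not given.

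Evx1as is the antisense neighbour of the homeobox gene Evx1. In the embryo tables (mm10) Evx1as (5730457N03Rik, ENSMUSG00000086126.1) lies on chromosome 6 from 52308389 to 52314832. It overlaps the start of Evx1 (ENSMUSG00000005503.8), which spans 52313498 to 52318378. The culture tables place the pair at 52258383 to 52264826 and 52263492 to 52268372.

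The first comparison asks how cultures of the 4x polyA knock-in line differ from those of the wild-type line in cells leaving pluripotency. P-values over these cultures measure the spread of cultures within a line. They cannot separate the knock-in from other differences between the lines. The labels do not give the insertion site, and the series title ties the study to Evx1as. A polyadenylation cassette ends transcripts that run into it. Evx1as was at 5.26 ± 1.14 FPKM in wild-type cultures and 0.0947 ± 0.037 in knock-in cultures (SD, n = 3 each) and fell by 2.50 on the log2 scale (limma, BH-adjusted p = 0.000302). Evx1 went from 30.5 ± 7.35 to 1.59 ± 1.08 FPKM and fell by 3.65 (adjusted p = 0.000299). With a pseudocount of 0.1 the log2 changes were -4.775 for Evx1as and -4.33 for Evx1, so which fell more is open. The exact permutation test of each gives p = 0.1, the smallest that 3 against 3 allows.

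Genes of the primitive streak, the site where epiblast cells become mesoderm and endoderm, were far lower in the knock-in cultures. The T-box gene T (brachyury) went from 155 ± 39.7 to 10.7 ± 5.13 FPKM (log2 change -3.79, adjusted p = 0.000298). Mixl1, a homeobox gene of mesendoderm, went from 49.9 ± 15.5 to 2.50 ± 0.649 (log2 change -3.84, adjusted p = 0.000129). Of the 18 measured members of the primitive streak list 12 fell, 2 rose and 4 did not pass the test, and adjustment over the list alone gave the same counts of 12 and 2. The camera test placed the list below other genes (adjusted p = 3.46e-05), a call that ended with an estimated correlation (adjusted p = 0.315). The members that rose were Wnt8a (log2 change 2.04) and Foxa2 (1.89), which mark the early and the anterior streak. Eomes, Nodal and Lefty2, all tied to NODAL signalling, had log2 changes of 0.13, -0.02 and 0.15 and did not pass. Other NODAL targets did change: of 12 measured, 2 rose and 3 fell, Mixl1 among the latter.

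Genes of the late, posterior part of the streak fell too. Of 13 measured members of its list 10 fell and 3 did not pass, with the same 10 when adjusted over the list alone (camera adjusted p = 2.49e-07, and adjusted p = 0.249 with an estimated correlation). Msx2, a target of BMP signalling, went from 39.0 ± 8.26 to 1.86 ± 1.05 FPKM and Cdx1, a regulator of posterior identity, from 16.8 ± 5.49 to 0.779 ± 0.354. Cdx2 went from 19.6 ± 8.48 to 0.333 ± 0.349.

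Nascent mesoderm followed. Of 18 measured members 9 fell, 3 rose and 6 did not pass (10 and 3 adjusted over the list alone; adjusted p = 0.00268, and adjusted p = 0.315 with an estimated correlation). Msgn1, a regulator of presomitic mesoderm, was at 6.58 ± 2.10 FPKM in wild-type cultures and listed at 0 in all 3 knock-in libraries. Hand1 went from 15.7 ± 4.54 to 1.88 ± 0.152 FPKM. WNT targets fell in 10 of 14 members and 1 rose, with the same counts adjusted over the list alone and 10 and 0 after scaling (adjusted p = 0.000458, and adjusted p = 0.249 with an estimated correlation). Sp5 went from 176 ± 28.4 to 20.2 ± 8.49 FPKM. BMP targets fell in 6 of 11 and 1 rose (7 and 1 adjusted over the list alone; adjusted p = 0.00202, and adjusted p = 0.249 with an estimated correlation). The largest fall of all named genes was in Wnt6, a WNT ligand, from 177 ± 45.0 to 1.09 ± 0.986 FPKM (log2 change -6.48). Fn1, the matrix protein fibronectin, went from 205 ± 28.4 to 25.2 ± 2.00 FPKM.

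Epiblast genes moved the other way. Of 16 measured members of the primed epiblast list 13 rose, 2 fell and 1 did not pass, the same when adjusted over the list alone (adjusted p = 7.41e-05, and adjusted p = 0.315 with an estimated correlation). Dnmt3b, a DNA methyltransferase of the epiblast, went from 30.6 ± 4.40 to 206 ± 21.0 FPKM (log2 change 2.72, adjusted p = 7.57e-05), Utf1 from 148 ± 14.3 to 655 ± 48.3 and Pou3f1 from 93.9 ± 15.6 to 212 ± 7.61. The pluripotency factor Sox2 went from 33.9 ± 5.73 to 84.0 ± 3.16 FPKM, and Foxd3, which maintains pluripotent cells, from 1.35 ± 0.342 to 31.5 ± 3.39. In the naive pluripotency list 9 of 14 members rose, 3 fell and 2 did not pass, and 9 rose and 4 fell when adjusted over the list alone and 7 and 4 after scaling, while its test did not pass (adjusted p = 0.122). Dppa5a rose (log2 change 3.18, adjusted p = 0.000439), and Klf5 fell from 235 ± 2.90 to 64.0 ± 8.21. The largest rise was in Pla2g1b, a secreted phospholipase, from 2.01 ± 0.777 to 115 ± 7.13 FPKM (log2 change 5.31).

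Other cell types were looked for in the same way. Of 7 neuroectoderm genes 4 rose and 3 did not pass, and 1 was lower after scaling (adjusted p = 0.0956), Zic1 among them from 0.0886 ± 0.0314 to 3.40 ± 1.63 FPKM. Of 13 trophoblast genes 8 fell and 2 rose (adjusted p = 0.0252), of 6 visceral endoderm genes 4 fell (adjusted p = 0.046), of 14 epithelial genes 9 fell (adjusted p = 0.000663) and of 12 genes of the epithelial to mesenchymal transition 7 fell and 2 rose (adjusted p = 0.00202). In the hypoxia and glycolysis list 11 of 18 rose and 2 fell (adjusted p = 0.00268). None of these 5 passed with an estimated correlation (adjusted p = 0.315 or 0.384). Feeder fibroblast genes (1 higher and 3 lower of 5, adjusted p = 0.0956), organizer and definitive endoderm genes (3 and 7 of 11, adjusted p = 0.139), germ cell genes (2 and 5 of 8, adjusted p = 0.173), FGF targets (4 and 4 of 15, adjusted p = 0.519), stress genes (4 and 6 of 15, adjusted p = 0.334), mitochondrial genes (0 and 0 of 13, adjusted p = 0.519) and NODAL targets (2 and 3 of 12, adjusted p = 0.748) did not pass as lists. The NODAL list had a median log2 change of 0.08 and a mean of -0.23. Of the blood list only 2 members were measured, and the list was not tested.

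**Figure D1:**
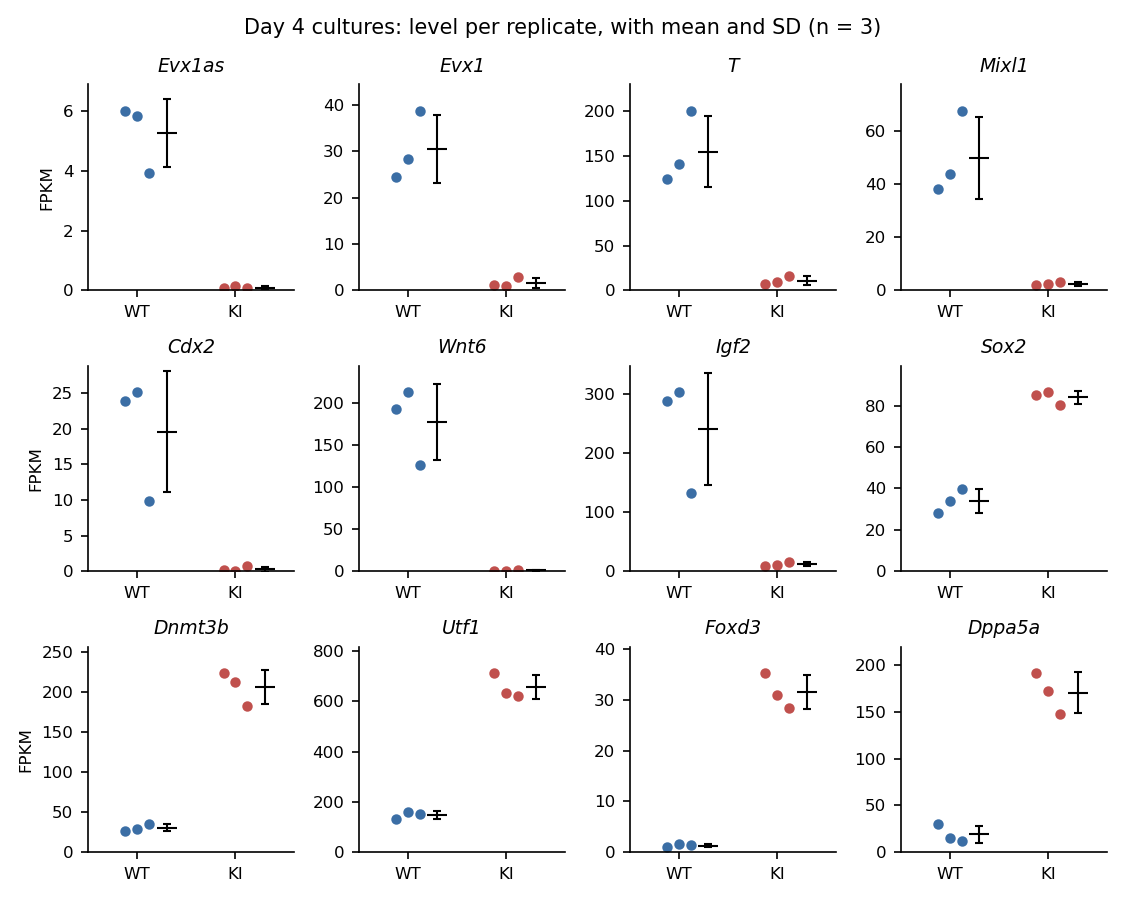
FPKM of 12 genes in each of the 3 wild-type (WT, blue) and 3 knock-in (KI, red) cultures on day 4, each panel with its own axis from 0; bars give the mean and SD. T sits at a mean of 155 in WT and 10.7 in KI, and Dnmt3b at 30.6 and 206.

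Over 13133 genes, 2134 were higher and 2122 lower in the knock-in (2099 and 2179 after scaling). The values of 6360 genes, 48.4%, did not overlap between the groups, where chance gives 10% for 3 against 3. Tokens in the names of the tables, read as sequencing lanes, put 1 wild-type and 2 knock-in libraries in lane 3, and within that lane the log2 change was -3.42 for T, -3.47 for Evx1 and 2.72 for Dnmt3b. Genes of chromosomes 1, 8 and 14 had median log2 changes of -0.40, -0.43 and -0.50 relative to all genes and those of chromosome 15 of 0.51, and without these chromosomes 1681 genes were higher and 1398 lower. Without knock-in replicate 2 the count was 2693.

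**Figure D2:**
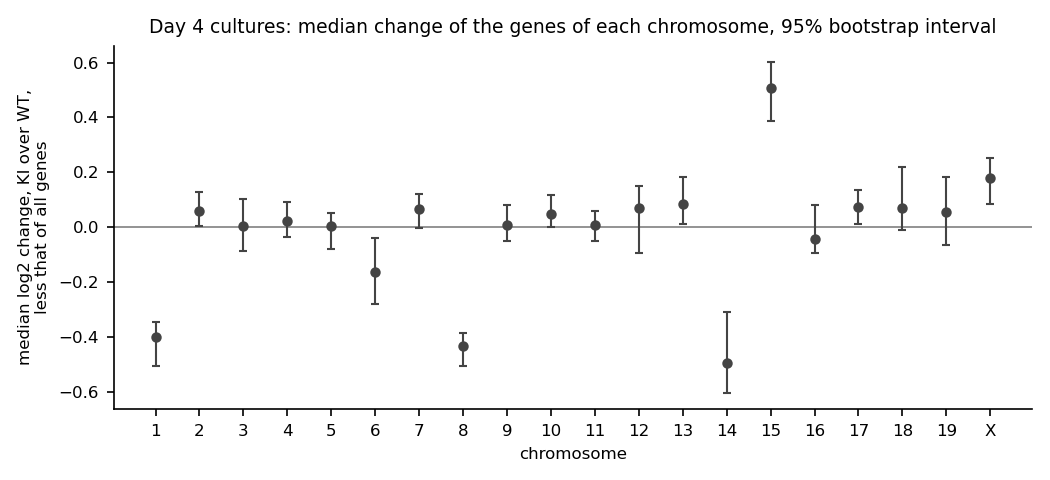
Median log2 change, knock-in minus wild-type cultures (n = 3 each), of the genes on each chromosome relative to the median of all genes, for 6075 genes at a mean of at least 10 FPKM; bars are 95% bootstrap intervals over genes. Chromosome 15 lies at 0.51 and chromosomes 1, 8 and 14 at -0.40, -0.43 and -0.50.

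The second comparison asks how streak sections of homozygous embryos differ from those of heterozygous ones. T was at 232 ± 69.4 FPKM in 6 heterozygous and 68.5 ± 22.5 in 5 homozygous sections (SD), lower in 5 of 5 layer-matched pairs, with a log2 change of -1.72 that did not pass as deposited (limma, BH-adjusted p = 0.0925). After scaling, the log2 change of T was -2.02 (adjusted p = 0.0012, with a range of 0.0012 to 0.618 over its alternatives). With the conflicting sections added by cell type label, which counts the heterozygous ones, low in T, as streak, the log2 change of T was -0.725. Hes7, an oscillating NOTCH target of presomitic mesoderm, fell from 11.5 ± 10.545 FPKM to 0.0306 ± 0.042 (log2 change -3.27, adjusted p = 0.0255), and Nkx1-2, a marker of the caudal epiblast, from 9.65 ± 4.14 to 1.18 ± 1.30 (log2 change -2.45, adjusted p = 0.0429). Both were lower in 5 of 5 pairs, and neither passed with layer as a block (adjusted p = 0.096 and 0.228). Fgf8, a growth factor of the streak, was at 6.71 ± 3.59 and 23.8 ± 9.16 FPKM, higher in 5 of 5 pairs, and did not pass (log2 change 1.84, adjusted p = 0.172).

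Of the 19 lists tested in streak, 7 passed with the preset correlation and 0 with an estimated one. Posterior streak genes lay below other genes (12 measured, 0 past over all genes, 2 higher and 4 lower adjusted over the list alone; adjusted p = 0.000314, and 0.127 as the adjusted p with an estimated correlation). NODAL targets lay above them (9 measured, 0 past, 5 higher and 0 lower adjusted over the list alone; adjusted p = 0.00171, and 0.127 as the adjusted p with an estimated correlation), as did primed epiblast genes (15 measured, 0 past, 6 and 0; adjusted p = 0.00892, and adjusted p = 0.430 with an estimated correlation). Lower than other genes were WNT targets (adjusted p = 0.026, and adjusted p = 0.152 with an estimated correlation), mitochondrial genes (1.21e-09 and 0.152 as the same adjusted p values), germ cell genes (0.0444 and 0.152) and nascent mesoderm genes (0.00892 and 0.430). The nascent mesoderm list had a median of 0.13 and a mean of -0.21. After scaling the germ cell call was lost (adjusted p = 0.102), and naive pluripotency, organizer and visceral endoderm genes lay above other genes (each adjusted p = 0.0364), none of them with an estimated correlation (adjusted p = 0.145, 0.536 and 0.627). Past over all genes after scaling were 2 primitive streak genes (1 as deposited), 2 posterior streak genes, 1 nascent mesoderm gene and 1 WNT target, all lower. These lists share members. The primitive streak list itself did not pass with the preset correlation (19 measured, adjusted p = 0.0623, and adjusted p = 0.137 after scaling).

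Of 9932 genes, Hes7 and Nkx1-2 were lower and 0 higher, with 1012 at an unadjusted p under 0.05. The median log2 change of all genes was 0.25, and after scaling 8 genes were lower and 0 higher. As sections may share an embryo, p-values over sections are too small. The count was 0 without heterozygous layer 7 or 9 or homozygous layer 1, 5, 7 or 11, and 9 without homozygous layer 9.

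The mesoderm sections were compared in the same way, with 3 heterozygous and 5 homozygous libraries. Tdgf1, the NODAL co-receptor Cripto, rose from 19.9 ± 8.15 to 101 ± 18.4 FPKM (log2 change 2.41, adjusted p = 0.0399), and Wnt3, a WNT ligand needed for the streak, from 0.646 ± 0.352 to 6.19 ± 3.24 (2.39, adjusted p = 0.0302). Dppa5a, a gene of pluripotent cells, rose from 0.374 ± 0.649 to 7.29 ± 3.12 FPKM (2.98, adjusted p = 0.0207), Ctsc from 0.604 ± 0.565 to 12.3 ± 5.45 (2.92, adjusted p = 0.0302) and Sgk1 from 1.29 ± 0.195 to 11.2 ± 3.95 (2.50, adjusted p = 0.0425). All 5 were higher in every homozygous than in every heterozygous mesoderm section. The lack of overlap was a condition for naming the largest changes, and 840 of 8695 genes (9.66%) had no overlap either way.

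With the preset correlation 6 of 20 lists passed, and 0 with an estimated one. NODAL targets lay above other genes (9 measured, 1 past, 6 higher and 0 lower adjusted over the list alone; adjusted p = 0.000109, and 0.266 as the adjusted p with an estimated correlation). So did the primitive streak list (12 measured, 1 past, 7 and 0; 0.00185 and 0.284 as the same adjusted p values) and the organizer and endoderm list (11 measured, 0 past, 7 and 0; 0.00342 and 0.462). Visceral endoderm genes, markers of the tissue around the epiblast, also lay higher, with a median log2 change of 1.77 over 13 genes (0 past, 5 and 0; 0.00126 and 0.524), as did naive pluripotency genes (4 measured, 1 past, 2 and 0; 0.00735 and 0.266). Mitochondrial genes lay lower (0.00586 and 0.524). All 6 lists also passed after scaling.

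Over 8695 genes 17 were higher and 0 lower, against 16 and 3 after scaling, with a median log2 change of all genes of 0.31. These p-values are too small if sections share an embryo. Leaving out 1 section gave between 0 genes (homozygous layer 7, 9 or 11) and 139 (homozygous layer 3).

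Both regions were then fitted together, with region and layer as terms, to use all 19 sections. Eomes, a T-box gene that acts early in mesendoderm, was at 11.2 ± 8.17 FPKM in 9 heterozygous and 34.6 ± 18.3 in 10 homozygous sections and rose (log2 change 1.95, adjusted p = 0.00319). Lhx1 went from 5.92 ± 8.14 to 31.7 ± 27.5 FPKM (2.07, adjusted p = 0.00319), Otx2 from 4.89 ± 4.17 to 20.2 ± 13.3 (1.75, adjusted p = 0.0252) and Gsc, a gene of the organizer, the streak's signalling centre, from 0.0974 ± 0.237 to 6.73 ± 8.65 (1.88, adjusted p = 0.0104). Eomes, Lhx1 and Otx2 were higher in 8 of 8 layer-matched pairs and Gsc in 7 of 8. Hoxb1, a homeobox gene of the posterior streak, fell from 13.2 ± 12.1 to 1.25 ± 1.36 FPKM (log2 change -2.09, adjusted p = 0.00896) and Hoxb2 from 7.57 ± 6.54 to 0.616 ± 0.857 (-1.86, adjusted p = 0.0104), in 8 of 8 and 7 of 8 pairs.

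T fell from 159 ± 123 to 38.1 ± 35.3 FPKM, in 7 of 8 pairs (log2 change -1.22, adjusted p = 0.0299). Its adjusted p lay between 0.0526 and 0.0782 without any 1 of 6 sections. With the conflicting sections added by cell type label, which counts the heterozygous ones as streak, its adjusted p was 0.523 and its log2 change -0.529. With those sections added by title they were 0.00849 and -1.266. Hes7 fell from 7.82 ± 9.97 to 0.04 ± 0.0793 (-2.16, adjusted p = 0.0106). Fgf8 rose from 4.88 ± 3.95 to 17.5 ± 10.4 FPKM (1.88, adjusted p = 0.004). Of 10 NODAL targets 5 rose, Eomes, Tdgf1, Gsc, Mixl1 and Skil, and 5 did not pass, with 6 higher and 0 lower adjusted over the list alone and 4 higher after scaling. The camera test placed the list above other genes with the preset correlation (adjusted p = 1.74e-05) and with an estimated one (adjusted p = 0.0149). Tdgf1 went from 63.6 ± 54.1 to 146 ± 71.4 FPKM and the epiblast factor Utf1 from 2.37 ± 1.76 to 7.47 ± 4.61, both higher in 8 of 8 pairs. Smad1, which carries BMP signals, went from 2.67 ± 0.77 to 8.58 ± 2.35 FPKM and Pou5f1, a pluripotency factor, from 52.1 ± 35.2 to 91.8 ± 57.4.

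Of the primitive streak list 6 of 19 rose, 1 fell and 12 did not pass, against 7 higher and 4 lower adjusted over the list alone, and its test did not pass (adjusted p = 0.930). After scaling 4 were higher and 2 lower. Of the organizer list 3 of 16 rose (7 and 0 adjusted over the list alone; adjusted p = 0.0536), a list that passed after scaling (adjusted p = 0.00464, and adjusted p = 0.558 with an estimated correlation), and of 12 posterior streak genes 1 rose and 2 fell (2 and 3; adjusted p = 0.0536). Of 13 mitochondrial genes mt-Nd6 fell, from 341 ± 93.8 to 200 ± 34.2 FPKM (0 and 6 adjusted over the list alone; adjusted p = 2.47e-10, and adjusted p = 0.0985 with an estimated correlation), and after scaling 7 of the 13 were lower. Visceral endoderm genes lay higher, with 0 of 14 past (adjusted p = 0.0335, and adjusted p = 0.542 with an estimated correlation).

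Evx1as was at 0.962 ± 1.46 FPKM in the 9 heterozygous and 0.0214 ± 0.0514 in the 10 homozygous sections. A two-sided permutation test within regions gave p = 0.00425 (BH-adjusted p = 0.034 over 8 such tests). Evx1 was at 2.49 ± 2.82 and 1.45 ± 1.53 FPKM, and its exact permutation p was 0.632. In streak alone Evx1as was at 1.21 ± 1.76 and 0.0428 ± 0.0693 FPKM with an exact permutation p of 0.0931, and Evx1 at 3.39 ± 3.13 and 1.98 ± 2.03 with p = 0.491. In mesoderm the exact p was 0.107 for Evx1as, which was listed at 0 in all 5 homozygous sections, and 0.786 for Evx1.

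**Figure D3:**
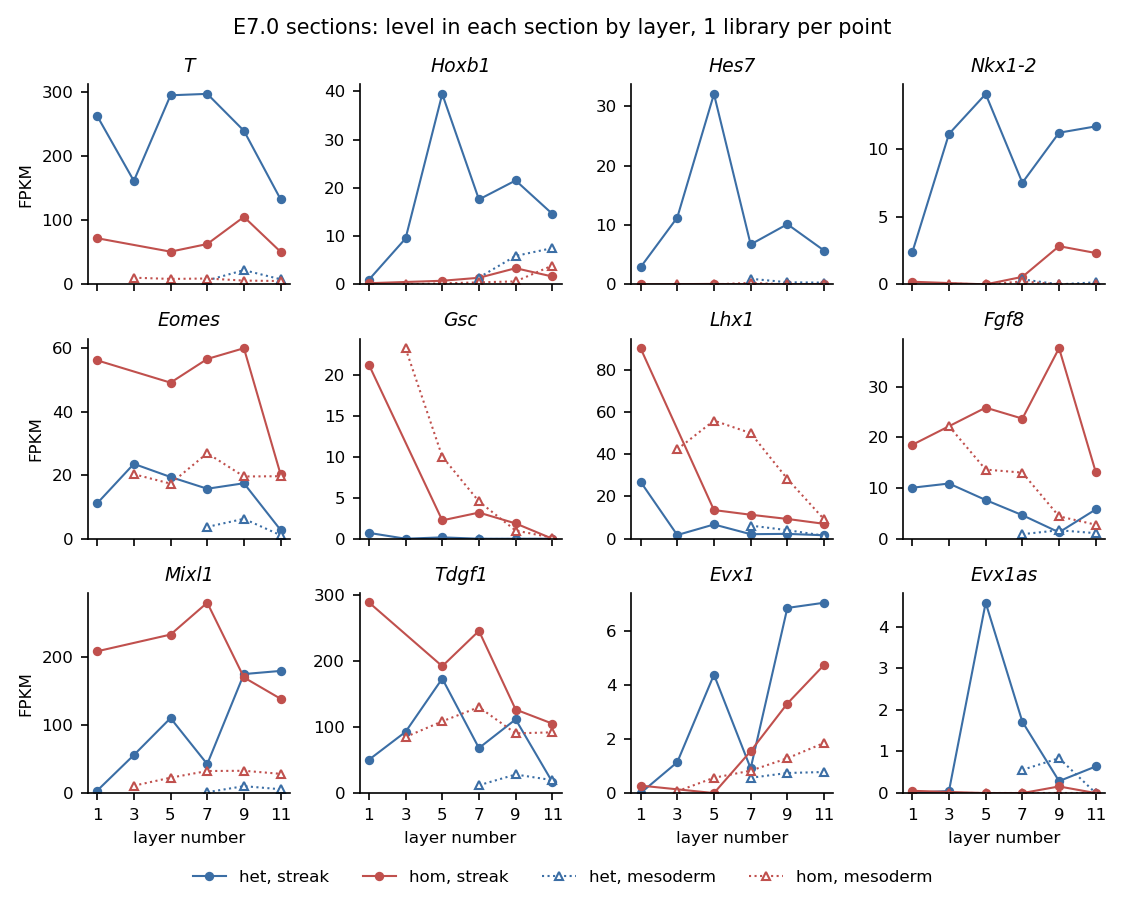
FPKM of 12 genes by layer number in heterozygous (het, blue) and homozygous (hom, red) sections of streak (filled circles) and mesoderm (open triangles), 1 library per point, each panel with its own axis from 0. T lies lower in homozygous streak in 5 of 5 layer-matched pairs, and Eomes higher in homozygous sections in 8 of 8 pairs over both regions.

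Over 9527 genes 108 were higher and 11 lower in homozygous sections, with a median of all genes of 0.24. After scaling 94 were higher and 71 lower, and 89 genes were called both ways. P-values here are too small, as sections may share an embryo. Leaving out 1 section gave 43 genes (homozygous mesoderm layer 11) to 577 (homozygous mesoderm layer 3), and adding the conflicting sections 818 by title and 835 by cell type label. By the tokens read as lanes, the conflicting sections were in lanes 5 and 6 and the other sections in lane 2. The heterozygous ones had Yam1 at 38.3% and 26.9% of FPKM. What these differences add to the counts was not tested.

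Whether the effect of genotype differs between mesoderm and streak was tested directly. No gene of 9527 passed, with 337 at an unadjusted p under 0.05 in limma. Among streak genes, T had a genotype effect higher in mesoderm by 1.22 on the log2 scale and Hoxb2 by 1.77, neither past the test, and Evx1 by 1.18 (adjusted p = 0.999). As lists, primitive streak genes (19 measured, median difference 0.57, 3 higher adjusted over the list alone), posterior streak genes (12 measured, median 1.08, 0 adjusted over the list alone) and WNT targets (12 measured, median 0.47, 2 higher) lay above other genes with the preset correlation (adjusted p = 6.2e-06, 2.35e-05 and 0.00404) and with an estimated one (adjusted p = 0.0357, 0.0288 and 0.0288). With scaling and an estimated correlation the WNT call was lost (adjusted p = 0.0669). Blood genes (3 measured, median 1.51, adjusted p = 0.0049) and germ cell genes (4 measured, median 0.63, adjusted p = 0.0188) passed with the preset correlation and not with an estimated one (adjusted p = 0.113 and 0.075), and the germ cell call was lost after scaling (adjusted p = 0.06355). Sections may share an embryo, so these p-values are too small.

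The comparison of regions asks what sets mesoderm apart from streak at the same layer and genotype, over 7 pairs of sections. Streak genes were far lower in mesoderm. T fell from 134 ± 98.0 to 9.29 ± 5.89 FPKM (log2 change -3.54, adjusted p = 0.000118), Mixl1 by a log2 change of -3.43 (adjusted p = 0.000118) and Fst, an inhibitor of activin, from 84.5 ± 19.0 to 6.44 ± 5.43 (-3.74, adjusted p = 0.000112), each in 7 of 7 pairs. Cdh1, the epithelial cadherin, fell from 15.1 ± 4.60 to 2.35 ± 2.36 FPKM (-2.52, adjusted p = 0.00477) and the peptide gene Apln from 15.4 ± 7.37 to 0.655 ± 0.308 (-3.18, adjusted p = 0.000118). Genes of mesoderm rose: Gata6 from 0.565 ± 0.608 to 4.76 ± 2.25 FPKM (1.87, adjusted p = 0.00302), Kdr, a receptor of blood vessel precursors, from 0.338 ± 0.682 to 3.68 ± 3.91 (1.58, adjusted p = 0.0169) and Twist1 from 0.545 ± 0.732 to 3.02 ± 1.55 (1.40, adjusted p = 0.0163), each in 7 of 7 pairs. Evx1 was at 3.49 ± 2.83 FPKM in streak and 0.947 ± 0.468 in mesoderm and did not pass (-0.91, adjusted p = 0.114).

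Of 19 primitive streak genes 12 fell and 1 rose, or 14 and 2 adjusted over the list alone and 4 and 0 after scaling (adjusted p = 1.82e-05, and adjusted p = 0.0977 with an estimated correlation). Of 11 WNT targets 6 fell (8 adjusted over the list alone, 2 after scaling; 1.82e-05 and 0.0909 as the same adjusted p values), among them Sp8, from 15.5 ± 8.35 to 1.14 ± 0.237 FPKM. The nascent mesoderm list held with both correlations (adjusted p = 5.79e-11 and 0.0351): 6 of 21 members rose, 0 fell and 15 did not pass, or 7 and 1 adjusted over the list alone and 4 and 0 after scaling. Organizer and endoderm genes lay above other genes (3 of 11 higher, 6 adjusted over the list alone, 1 after scaling; adjusted p = 7.14e-11, and adjusted p = 0.0909 with an estimated correlation), with Cxcr4 from 0.218 ± 0.23 to 3.14 ± 1.63 FPKM. Of 5 naive pluripotency genes 3 fell, or 2 after scaling, with a log2 change of -1.77 for Pou5f1 (list adjusted p = 0.00184, and adjusted p = 0.0909 with an estimated correlation). Of 20 lists 12 passed with the preset correlation and 1, nascent mesoderm, with an estimated one. Markers of another endoderm, the visceral endoderm, also lay above other genes, with 0 of 14 past and 1 higher after scaling (adjusted p = 6.47e-05, and adjusted p = 0.352 with an estimated correlation). So did genes of the epithelial to mesenchymal transition (3 of 12 higher and 1 lower, 2 and 0 after scaling, 0.000383 and 0.0977 as the same adjusted p values), BMP targets (1 of 6 higher, 0.0122 and 0.132), trophoblast genes (2 of 5 higher and 2 lower, 0.0413 and 0.132) and neuroectoderm genes (0 of 3 past, 0.0352 and 0.132). Posterior streak genes (5 of 13 lower, 1 after scaling, 0.0413 and 0.352) and hypoxia and glycolysis genes (2 of 14 lower, 0 after scaling, 0.0413 and 0.541) lay below. After scaling the calls of trophoblast (1 higher and 0 lower, adjusted p = 0.32), neuroectoderm (adjusted p = 0.1005) and hypoxia and glycolysis genes (adjusted p = 0.167) were lost, and FGF targets lay below other genes (adjusted p = 0.0141, and adjusted p = 0.0958 with an estimated correlation). With scaling and an estimated correlation 4 lists passed, nascent mesoderm, primitive streak, WNT targets and naive pluripotency (each adjusted p = 0.0451).

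Over 9146 genes 53 were higher and 735 lower in mesoderm, with a median log2 change of all genes of -0.34. After scaling 35 were higher and 28 lower, 60 of them called both ways, T, Mixl1, Fst, Apln, Sp8, Cdh1, Gata6, Kdr and Twist1 included. The p-values are too small, as sections may share an embryo. Without homozygous layer 7 the count was 158.

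Along the layers of the streak, with genotype as a term, the question is which genes change with position. Phlda2, an imprinted growth regulator, rose by 0.54 per layer on the log2 scale (limma adjusted p = 0.00855). Ndrg1 (-0.54 per layer, adjusted p = 0.00473), the neuropeptide gene Trh (-0.46, adjusted p = 0.0086), Fgf5, a growth factor of the epiblast (-0.41, adjusted p = 0.00473), and Socs2 (-0.27, adjusted p = 0.0108) fell. Evx1 had a slope of 0.26 per layer and did not pass (adjusted p = 0.0983).

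The posterior streak list rose with layer as a group with both correlations (adjusted p = 5.12e-11 and 0.00954): of 12 genes 0 passed over all genes and 8 rose adjusted over the list alone, with slopes of 0.26 for Cdx2 and 0.28 for Hoxb2. The organizer and endoderm list went the other way, with 1 of 15 lower, Trh, and 13 lower adjusted over the list alone (adjusted p = 3.5e-09, and adjusted p = 0.228 with an estimated correlation). Lhx1 had a slope of -0.29, Cer1 of -0.42 and Otx2 of -0.18. Layer 1 stood apart in Cer1, at 39.32 FPKM in heterozygous and 39.58 in homozygous streak, against at most 0.7671 and 0.153 in other layers. Lhx1 was at 26.97 and 90.17 in layer 1, against at most 6.747 and 13.57. These slopes thus rest largely on layer 1, and the list was not tested without it. BMP targets (6 measured, adjusted p = 0.00017), WNT targets (12, adjusted p = 0.0172) and primitive streak genes (19, adjusted p = 0.0194) lay above other genes and epithelial genes (11, adjusted p = 0.00828) below, none with an estimated correlation (adjusted p = 0.259, 0.228, 0.446 and 0.446). After scaling the call of the primitive streak list was lost (adjusted p = 0.0787), and hypoxia and glycolysis genes lay above other genes (adjusted p = 0.0396, and adjusted p = 0.427 with an estimated correlation). In each of the posterior streak and BMP lists 1 gene was then higher.

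Of 9932 genes 1 rose and 7 fell along the layers (3 and 7 after scaling). Sections may share an embryo and the p-values are too small. Without the layer 1 sections 1 gene passed, Phlda2, and without layer 11 also 1.

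The slope along the layers was tested for a difference between genotypes, and 0 of 9932 genes passed in limma, with 543 at an unadjusted p under 0.05. Mixl1 had a slope lower in homozygous streak by 0.49 per layer, and Pcdh7 by 0.34 (both adjusted p = 0.815), and the difference for Evx1 was -0.03 (adjusted p = 0.979). Only the organizer and endoderm list passed with the preset correlation (15 measured, median difference -0.01, 0 past; adjusted p = 0.0228) and neither with an estimated one (adjusted p = 0.945) nor after scaling (adjusted p = 0.298). Sections may share an embryo here too.

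The anterior epiblast was captured once per genotype, so values are given without a test. Homozygous FPKM values were 1.3 times as high over all genes by median ratio, with a median log2 difference of 0.33 over 9202 genes as deposited and 0.04 after scaling. Yam1 took 29.3% of FPKM in the heterozygous and 5.96% in the homozygous library. A smaller share of Yam1 leaves more FPKM to the other genes. The difference over all genes is thus no measure of higher levels in the homozygote. Among genes at 20 FPKM or more, Prps1l3 (0.6 and 35.2 FPKM), Dcp2 (0.537 and 20.6) and Nmt2 (2.69 and 28.8) were among the 5 highest in the homozygous library. Mrpl52 (27.95 and 0.658 FPKM), Hist2h2ac (20.7 and 0.42) and Hist2h2aa1 (21.9 and 1.35) were among the 5 lowest. The medians of 12 gene lists, as deposited, ran from -0.31 for germ cell genes to 1.44 for FGF targets, against 0.33 for all genes. Among 10000 random lists matched on expression, these medians stood at percentiles 12.57 and 98.55. Without replicates the percentiles do not measure a spread between embryos. Evx1 was listed at 0 in both, and Evx1as at 0.111 and 0 FPKM.

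The last comparison asks whether genes that differ between the knock-in and wild-type cultures move in the homozygous sections. Differences between the lines other than the knock-in may be among them. Of 2134 genes higher in culture 1433 were measured in the sections of both regions, with a median log2 change of 0.29 against 0.24 for all genes. Of 2122 lower in culture 1151 were measured, with a median of 0.22. Neither set passed in streak, mesoderm or both regions (camera adjusted p from 0.511 to 0.848 with the preset correlation and 0.968 with an estimated one). T was lower in both settings, while Eomes, which rose in the sections, had a log2 change of 0.13 in culture. Mixl1 went opposite ways, falling in culture and rising in the sections of both regions (log2 change 2.03). Evx1 had a log2 change of -3.65 in culture and of -0.14, not past, in the sections of both regions.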

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

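Of the tests below, the one of streak tissue in mesoderm sections was chosen after the result was seen. Among 57 genes and the library totals, a sample standing far from the others of its group was found in 41 of 186 groups tested, where chance gives about 1 in 20. The genes were narrowed to those the text may name after a wider screen had been seen, so this share is no test. Over all 363 genes whose levels were tabulated, 317 of 1089 groups (29.1%) had such a sample. Groups ordered along an axis are spread by their position too.

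Layer 1 of the streak stood apart in many genes. In the homozygous layer 1 section Lhx1 was at 90.17 FPKM (nearest other section 13.57), Gsc at 21.2 (3.183), Utf1 at 18.66 (7.33), Gata6 at 6.493 (1.781), Cxcr4 at 2.533 (0.5954), Cer1 at 39.58 (0.153), Krt8 at 53.19 (7.454), Cdh2 at 13.99 (3.701), Ndrg1 at 32.49 (4.41), Trh at 330.5 (75.68) and Fgf5 at 60.47 (15.74). In the heterozygous layer 1 section Lhx1 was at 26.97 FPKM (6.747), Gsc at 0.7124 (0.1643), Gata6 at 3.313 (0.7164), Cer1 at 39.32 (0.7671), Krt8 at 79.53 (12.67), Krt18 at 58.68 (3.498), Cdh2 at 14.79 (4.56), Ndrg1 at 73.31 (9.185), Fgf5 at 47.44 (13.22), Socs2 at 51.01 (19.53) and Ctsc at 16.28 (6.483).

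Other streak sections stood apart in single genes. Hes7 was at 32.08 FPKM and Tbx6 at 29.17 in heterozygous layer 5, against 11.26 and 11.6 in the nearest sections, and Cxcr4 at 0.245 in heterozygous layer 9, against 0. The mitochondrial gene mt-Nd6 was at 510.3 FPKM in heterozygous layer 11 (nearest 330.3). In homozygous streak Eomes was low in layer 11, at 20.21 FPKM (nearest 49.1). Hand1 was at 3.684 and Kdr at 1.866 in that section, Twist1 at 1.917 in layer 5 and Tbx6 at 4.638 in layer 7.

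In homozygous mesoderm, layer 11 stood apart in Hand1, at 29.99 FPKM (nearest 2.54), and Hoxb1, at 3.895 (0.6145). Layer 3 stood apart in Laptm4b, at 6.03 (24.03), Sp5, at 20.29 (9.574), Ndrg1, at 1.664 (0.2917), and Yam1, at 22.22% of FPKM (10.41%). Layer 7 had Hes7 at 0.2467 FPKM, Nkx1-2 at 0.2126 and an FPKM total of 252900 (nearest 230100). Trh was at 238.3 FPKM in layer 5 (73.64).

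The genotype effect differed between mesoderm and streak in 5 lists tested as such with the preset correlation. The median difference was 0.5742 for primitive streak genes, 1.084 for posterior streak genes, 1.509 for 3 blood genes, 0.6331 for 4 germ cell genes and 0.4697 for WNT targets. Primitive streak, posterior streak and WNT lists passed with an estimated correlation too (adjusted p = 0.0357, 0.0288 and 0.0288), but the WNT list not after median-ratio scaling (adjusted p = 0.0669), and sections may share an embryo.

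Levels near the floor in mesoderm, where a fall has little room, may account for part of the difference in the primitive and posterior streak lists. The 5 members at 5 FPKM or more in heterozygous mesoderm kept a median difference of 0.569 above all genes, against 0.84 for all members, which met the bound set for excluding a floor, but they run from 1.22 for T to -0.47 for Id1 and leave the question open. Streak tissue in the homozygous mesoderm sections may also raise streak genes there: of 55 genes lower in mesoderm than streak in the homozygous pairs, 52.7% lay above the median of all genes in homozygous minus heterozygous mesoderm, against 48.9% of genes in neither set and 91.3% of 312 genes chosen in the heterozygous pairs. Noise in the libraries shared by choice and test lowers the share from homozygous pairs and raises that from heterozygous ones, so neither decides, nor do single markers (T -0.57, Fst 0.04, Sp8 -0.09 and Mixl1 2.55, none past the test). A genotype effect that differs by region stays open beside both.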

How the results depend on the processing

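Scaling for the list tests, leaving out the heterozygous layer 11 sections, leaving out Yam1 or the genes of 4 chromosomes, and centring chromosomes were tests chosen after the data had been seen. Over 4589 alternatives, 3942 were labelled as unchanged, 526 lost the call, 25 gained it, 91 moved a count or value and 5 turned a direction. For genes, unchanged means the same direction and side of the threshold. A count could change within a fold bound, as from 4256 to 2903 without wild-type replicate 1. For lists it means the same side of the threshold. A list direction that turned while neither test passed was not counted, and direction was not compared for the estimated correlation. Where a value differs below, the cause was not tested, except that fewer sections or a changed set of genes tested alter the power by construction. Depth is unknown, so what it limits cannot be given. A fit to counts was not run, for lack of counts.

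The culture count of 4256 was 2693 without knock-in replicate 2 and up to 3976 without another (knock-in replicate 3). It was 3079 without chromosomes 1, 8, 14 and 15 and 3804 with chromosomes centred.

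The streak count of 2 was 0 with a pseudocount of 5, no filter, a filter at 5, layer as a block or the conflicting sections by cell type label. It was 1 with a pseudocount of 0.1, no mean-dependent prior or no layer term, 4 with those sections by title, 8 with median-ratio scaling, 9 with quantile scaling and 6 without heterozygous layer 11. Leaving out 1 section gave 0 (heterozygous layers 7 and 9, homozygous 1, 5, 7 and 11), 1 (heterozygous 3 and 5), 5 (heterozygous 1), 6 (heterozygous 11) or 9 (homozygous 9).

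The mesoderm count of 17 was 0 with a pseudocount of 5, no filter or a filter at 5, 6 with quantile scaling or by cell type label, 40 with layer as a block, 60 with no layer term and 227 by title. Leaving out 1 section gave 0 (homozygous 7, 9 and 11), 4 (homozygous 5), 32 and 40 (heterozygous 7 and 9) or 139 (homozygous 3).

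The count of 119 for both regions was 19 with no filter, 192 with a filter at 5, 210 with quantile scaling, 818 by title, 835 by cell type label, 58 without heterozygous layer 11 and 197 without Yam1. Leaving out 1 streak section gave 275, 208, 57 and 343 (heterozygous 1, 5, 7 and 9) and 49, 73 and 45 (homozygous 7, 9 and 11). Leaving out 1 mesoderm section gave 58 and 46 (heterozygous 7 and 11) and 577, 74, 58, 66 and 43 (homozygous 3, 5, 7, 9 and 11), a range of 43 to 577.

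The count of 0 for the difference between regions (limma, 337 at an unadjusted p under 0.05) was 1 with no filter, median-ratio or quantile scaling, and 0 to 1 with a section left out. The region count of 788 was 37 with no filter, 63 with median-ratio scaling, 73 with quantile scaling, 346 with no mean-dependent prior, 1723 over all 19 sections, 2214 by title and 88 without Yam1. It was 158, 296 and 356 without homozygous layers 7, 9 and 11 and 342 and 326 without heterozygous layers 7 and 9, within a range of 158 to 743.

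The trend count of 8 was 0 with no filter, 5 with a filter at 5, 1 without layer 1, 1 without layer 11 and 25 by title. It was 3 and 5 without the heterozygous or homozygous layer 1 section, 21 without heterozygous layer 3 and 18 without homozygous layer 11. The count of 0 for the difference in trend (limma, 543 at an unadjusted p under 0.05) was 1 without homozygous layer 1 and 0 without each other section. Of 52 list calls, 6 held with an estimated correlation, with 0 others gained. With shared members removed 34 passed: 27 held and 7 others were gained, while 14 were lost and 11 could not be tested. After median-ratio scaling 51 passed, 45 held and 6 gained, and 8 held after scaling with an estimated correlation. The anterior pair had a median log2 difference of 0.03564 with median-ratio scaling, against 0.33.

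In culture the log2 change was -2.50 for Evx1as and -3.65 for Evx1, and -4.775 and -4.33 with a pseudocount of 0.1. Evx1 turned direction 5 times, never past the test. For both regions it was -0.14, with a range of -0.438 (quantile scaling) to 0.044 (by cell type label) over its alternatives. Within that range, leaving out 1 section gave -0.275 (heterozygous mesoderm layer 11) to 0.022 (homozygous streak layer 5). In mesoderm it was 0.10, and -0.028 with a pseudocount of 0.1. Its difference in trend was -0.025, with -0.0563 without homozygous layer 5, 0.031 without heterozygous layer 1 and 0.14 without homozygous layer 1.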

Other observations

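Of the tests in this part, those of a few changed genes, of copy number and of the layers of organizer and posterior streak genes were chosen after the result was seen. In the 3 sections with conflicting region labels, the homozygous one had Mixl1 at 226 FPKM, T at 39.8, Fst at 67.6 and Laptm4b at 9.33. The heterozygous ones had Mixl1 at 1.69 and 1.79, T at 21.0 and 8.34, Fst at 9.47 and 1.95 and Laptm4b at 20.8 and 17.9. Titles place the homozygous one in streak and the heterozygous ones in mesoderm, cell type labels the reverse. Homozygous mesoderm had Mixl1 at 25.4 ± 9.13, T at 7.82 ± 2.20 and Fst at 5.21 ± 1.31. Heterozygous mesoderm had 5.71 ± 4.47, 12.1 ± 8.81 and 7.69 ± 9.04. These 3 genes lie nearer the titles, without a test. Laptm4b, at 6.03 to 30.2 in homozygous mesoderm, does not tell for the homozygous one.

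Chromosomes 1, 8 and 14 lay lower and chromosome 15 higher in knock-in than wild-type cultures, by 0.757-, 0.742-, 0.709- and 1.42-fold, where the largest size of any other was 0.18 on the log2 scale. GC content is argued against, since at least 100.0% of each shift was left after its removal. At least 0.716 of the genes of each lay on its side, which largely follows from a shifted median and so says nothing on whether a few strongly changed genes take part. A hypothesis is that the cultures differ in the copy number of these chromosomes, for which 3 to 2 copies would give 0.667 and 2 to 3 copies 1.5. All 24 of 24 sixths of the chromosomes were shifted to their side, by at least 0.21, as were the genes of low, middle and high expression, but copy number was not measured.

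In both regions together 119 genes were called between genotypes. With the number of genes detected as a covariate the median called gene kept 0.752 of its log2 change, 0.738 among higher and 1.04 among lower genes. This argues against fewer genes detected in heterozygous libraries as the whole cause, and leaves a part open for the higher genes. Only 12 of 119 still passed, the median size going from 1.27 to 0.987 and its standard error from 0.279 to 0.292. Moving the homozygous layers by 2 or 4 left at least 0.889 of the median size of the 119 genes. For that set this argues against a linear trend with layer as the cause. Layer entered the fit as a straight line, so the move cannot show a position effect of another shape, such as that of layer 1. Homozygous layers lying at another position therefore stay open as a cause. For 6 called organizer and posterior streak genes the median kept 0.502, and Gsc, Lhx1 and Otx2 kept under 0.5. A difference between embryos other than genotype may account for the calls. After scaling, 84.6% of 104 called genes measured in the anterior pair went the same way there, 88 in number, which a genotype effect would give as well. The share over all genes was not computed. The anterior libraries also differ in genes at 1 FPKM or more (8344 heterozygous, 9577 homozygous) and in Yam1 (29.3% and 5.96% of FPKM). A difference between libraries could thus give the same agreement. The labels tie no section to an embryo, and genotype and embryo cannot be separated here.

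Other splits of the same samples were counted for each comparison. In culture the 10 splits are too few for a share under 0.05: the real one, 1 of the 10, gave 4256 genes and the highest other 2. In both regions together 1 of 100 splits, the real one, gave as many as 119 (highest other 3). Between regions 1 of 64 gave as many as 788 (highest other 4). These shares speak against a grouping by chance only if sections are independent. In streak 4 of 100 splits gave 2 genes or more, and in mesoderm 2 of 56 gave 17 or more. Other splits reached 1114 and 587 genes, so the samples have a structure besides genotype, and the streak count was 0 without heterozygous layer 7 or 9 or homozygous layer 1, 5, 7 or 11. These splits treat sections as independent, and sections may share an embryo. Chance is therefore not excluded by these shares for streak, for mesoderm, for both regions together or between regions. For the difference between regions 47 of 100 splits gave as many genes at an unadjusted p under 0.05 as the real 337 (highest other 1526), and for the difference in trend 40 of 100 as many as 543 (highest other 2080), so chance is not excluded for either.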
